A study of Mus musculus with 12 samples.

How the data were processed

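RNA was measured by sequencing in 12 libraries of mouse bone marrow-derived macrophages, the precursors of osteoclasts, from C57BL/6J mice. Per the labels, the cells were cultured for 2 days with M-CSF at 50 ng/mL, alone or with RANKL at 100 ng/mL, and the cultures with RANKL also received 1 µM BMS309403, 1 µM RHC80267 or no inhibitor. M-CSF is the survival factor of macrophages and RANKL is the cytokine that drives osteoclast formation. BMS309403 is known as an inhibitor of the fatty acid binding protein FABP4, and RHC80267 as an inhibitor of diacylglycerol lipase. Each of the 4 groups held 3 libraries. The labels do not say whether the 3 are separate cultures or animals, so p-values measure only the spread between these samples, which may be technical.

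The deposited table gives, per the file headers, a read count per gene and library. Between 9.49% and 9.89% of a library's values are not whole numbers, so they were read as RSEM expected counts made by the authors. The authors also deposited FPKM values per library, which were not used here. The authors' log2 fold changes and DESeq2 q-values (adjusted p-values) for 4 comparisons are in the deposited table, and only the number of genes they call is given here. Bowtie2, RSEM 1.3.1 and DESeq2 1.4.5 are named per the submitters' processing notes. The order of these tools and any filter on genes or reads are not given in the sources used here. Gene positions in the deposited table are on GRCm38, and 78.0% of the genes found in the reference annotation had the same start and end there. A position is not given for genes whose entry spans an unplaced sequence.

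The table holds 16570 genes, all typed as mRNA, and none from the mitochondrial genome. Total expected counts ranged from 17760844 to 18344989 per library. Expected counts were rounded to whole numbers, genes with low counts were removed with filterByExpr by group (4402 removed, 12168 tested), and libraries were scaled by TMM factors. All 12 libraries entered 1 quasi-likelihood fit with edgeR 4.0.16 under R 4.3.3, with group as the only term and 8 residual degrees of freedom. Each comparison is a contrast in that fit. A gene is called at a Benjamini-Hochberg adjusted p below 0.05 over all genes tested, and "rose" and "fell" are used of called genes. The biological coefficient of variation was 0.037. Levels are CPM (counts scaled by the TMM-adjusted library size), given as the mean ± SD over 3 libraries, and fold changes are on the log2 scale ± SE. All p-values are 2-sided, except the exact binomial p for stromal genes, which is 1-sided.

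A gene with no counts in a group was set to 3 counts over that group, which gives a lower bound on its fold. A gene with 1 to 3 counts in a group has its ratio with an exact 95% interval. Such bounds and intervals cover counting error only.

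The comparisons, the tests, 31 gene lists and the rule for naming genes were fixed before the data were examined. The rule names 12 fixed genes, the 6 highest and 6 lowest fold changes among called genes with a mean of at least 5 CPM in the higher group and no overlap between the libraries, and up to 4 members per list with the smallest p. Lists were tested with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01, adjusted over lists within a comparison. The count of members called is given also as adjusted over the list alone, and camera was repeated with the correlation estimated from the data. Members of a list are not independent of each other, and some genes are in more than 1 list.

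The fit was tested on simulated data with changes of known size. In a simulated BMS309403 comparison of 3 against 3 libraries, 73.1% of genes changed 1.25-fold were called, 86.6% of those changed 1.5-fold and 97.0% of those changed 2-fold, and a list of 25 other genes was raised 1.25-fold. Of the 202 calls, 171 and 22 were in these sets and 9 were false. Each gene was drawn independently, so these rates do not cover a shift of a whole library. Both inhibitor groups were compared with the same 3 RANKL libraries, which by itself makes their fold changes correlate. The correlation and covariance were therefore set beside 20 simulations in which both inhibitor groups were drawn from the RANKL means, with no inhibitor effect.

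Alternatives were DESeq2 1.42.0, RLE factors, no filter, a stricter filter (at least 1 CPM in at least 3 libraries), only the groups compared, limma-voom, a term for the replicate number, RANKL libraries split between comparisons, and each library left out in turn. Lists were also tested with fry, which asks whether the genes of a list move 1 way on balance and compares them with no other genes.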

Results

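Gene expression was measured in 12 libraries, 3 for each of 4 culture conditions: M-CSF alone, M-CSF with RANKL, and RANKL with either BMS309403 or RHC80267. Total expected counts per library were 18097537 to 18193362 with M-CSF, 17885762 to 18145377 with RANKL, 17939971 to 18344989 with BMS309403 and 17760844 to 17936609 with RHC80267. The first principal component held 71.1% of the variance and placed the M-CSF libraries at −71.3 to −69. On it the BMS309403 libraries stood at 6.8 to 10.5, the RANKL libraries at 16.4 to 21.9 and the RHC80267 libraries at 42.3 to 44.1. The second, with 15.5%, placed the RHC80267 libraries at 24.7 to 29.4 and the RANKL libraries at −18.8 to −16.1.

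The comparison of RANKL with M-CSF asks what 2 days of RANKL change in these macrophages. Several genes of the bone-resorbing osteoclast rose from low levels. Acp5, the tartrate-resistant acid phosphatase of osteoclasts, rose from 5.77 ± 0.509 to 2140 ± 211 CPM (SD, n = 3), and Ctsk, the protease cathepsin K, from 6.29 ± 2.12 to 2420 ± 290 CPM. Fabp4, a lipid carrier and the target of BMS309403, rose from 12.5 ± 1.38 to 36.4 ± 6.77 CPM. In the other direction, Il1b, which encodes the cytokine interleukin-1 beta, fell from 202 ± 39.3 to 2.36 ± 0.443 CPM, and Csf1r, the M-CSF receptor, from 4970 ± 138 to 2810 ± 20.4 CPM.

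Of 12168 genes tested, 3819 were higher and 3628 lower with RANKL, of which 790 and 337 changed more than 2-fold. Acp5 (gene 11433, chromosome 9, 22126727 to 22135746) changed by 8.54 ± 0.09 on the log2 scale (SE, adjusted p = 2.90e-25), and Ctsk (gene 13038, chromosome 3, 95499210 to 95509387) by 8.59 ± 0.13 (adjusted p = 4.32e-22). Nfatc1 (gene 18018, chromosome 18, 80606205 to 80713071), the main transcription factor of osteoclast formation, rose by 1.85 ± 0.06 (adjusted p = 1.36e-16). Mmp9, a matrix protease, rose by 6.33, and Dcstamp and Ocstamp, membrane proteins needed for cell fusion, by 6.12 and 7.69. Tnfrsf11a, the receptor RANK, rose by 0.81. Fabp4 (gene 11770, chromosome 3, 10196673 to 10208616) rose by 1.54 ± 0.14 (adjusted p = 2.73e-09) and its relative Fabp5 (gene 16592, chromosome 3, 10012585 to 10016610) by 0.87 ± 0.07 (adjusted p = 4.03e-10). Of the diacylglycerol lipases, Dagla rose by 1.04 and Daglb changed by −0.31.

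Several genes came from no or nearly no counts in M-CSF. Rufy4 was at least 910-fold higher, Mt3 at least 166-fold and Msln at least 117-fold higher with RANKL. Oscar, a co-stimulatory receptor of osteoclast precursors, was higher by a ratio of 1570 (95% interval 435 to 13000), Mst1r by 1200 (333 to 9950) and Calcr, the calcitonin receptor, by 1160 (208 to 45900). Csf3, the granulocyte growth factor, was at least 144-fold lower with RANKL. The other lowest values by the naming rule were Saa3 at −8.13, Ptgs2, the inducible cyclooxygenase, at −7.96, Cxcl1 at −7.38, Il1b at −6.42 and Cxcl3 at −6.20.

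Among the lists, 20 of 23 resorption genes rose and 3 fell (the same counts adjusted over the list alone, camera adjusted p = 3.00e-48). Of 18 subunits of the V-ATPase, the proton pump that acidifies the resorption space, 17 rose and 1 fell, also when adjusted over the list alone (adjusted p = 1.37e-19). Of 19 fusion genes, 15 rose and 2 fell, again the same adjusted over the list alone (adjusted p = 1.26e-17). The resorption, V-ATPase and fusion lists stayed called with an estimated correlation (adjusted p = 0.0078, 0.0078 and 0.0097). In the list of osteoclast transcription and RANK signalling, 16 of 29 rose and 11 fell, as also adjusted over the list alone (adjusted p = 2.04e-06), but adjusted p = 0.0703 with an estimated correlation. Jdp2 rose by 4.34, Ppargc1b by 3.13 and Fosl2 by 2.34. Of 32 nuclear genes of oxidative phosphorylation, 31 rose, as also adjusted over the list alone (adjusted p = 6.38e-22, adjusted p = 0.0514 with an estimated correlation), led by Cyc1 at 1.56 and Cycs, cytochrome c, at 1.43. Of 17 antigen presentation genes, 10 rose and 3 fell (10 and 4 adjusted over the list alone, adjusted p = 3.77e-05, adjusted p = 0.0514 with an estimated correlation), with the class II gene H2-Ab1 at 1.58 and its chaperone Cd74 at 1.69, and 5 fell without M-CSF replicate 2.

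Macrophage identity genes went down: 20 of 23 fell and 2 rose, as also adjusted over the list alone (adjusted p = 6.41e-20, adjusted p = 0.0078 with an estimated correlation), with Cx3cr1 at −1.76, Cd14 at −1.33, Apoe at −1.21 and Fcgr1 at −1.17. Of 16 targets of NRF2, the regulator of antioxidant genes, 15 fell and 1 rose, as also adjusted over the list alone (adjusted p = 3.48e-11, adjusted p = 0.0254 with an estimated correlation), among them Gclc at −1.45 and Gclm at −1.39, the subunits of the enzyme that limits glutathione synthesis. The 1 risen NRF2 target loses its call without M-CSF replicate 1, 2 or 3 or RANKL replicate 1, and the 1 risen interferon gene without M-CSF replicate 2. Of 24 cholesterol synthesis genes 18 fell, as also adjusted over the list alone (adjusted p = 1.41e-05, adjusted p = 0.218 with an estimated correlation), and of 24 interferon response genes 19 fell and 1 rose, as also adjusted over the list alone (adjusted p = 0.00846, adjusted p = 0.584 with an estimated correlation). In the NF-kB inflammatory list 15 of 24 fell and 7 rose (15 and 8 adjusted over the list alone, adjusted p = 0.0180, adjusted p = 0.348 with an estimated correlation), with Cxcl2 at −5.88, but Traf1 at 3.49 and Il1rn, the interleukin-1 receptor antagonist, at 2.26. Of 24 ribosomal protein genes 21 rose, as also adjusted over the list alone (adjusted p = 0.00551, adjusted p = 0.499 with an estimated correlation). In the list of diacylglycerol lipase, endocannabinoid and eicosanoid enzymes 15 of 27 fell and 9 rose, as also adjusted over the list alone (adjusted p = 0.0448, adjusted p = 0.147 with an estimated correlation). This call is lost without M-CSF replicate 3 (adjusted p = 0.0531) or RANKL replicate 1, 2 or 3 (adjusted p = 0.0521, 0.0528 and 0.0501). Among dendritic cell markers 5 of 12 rose, among them the osteoclast fusion gene Dcstamp, and 2 fell, as also adjusted over the list alone (adjusted p = 0.0234, adjusted p = 0.365 with an estimated correlation), and the call is lost without M-CSF replicate 3 (adjusted p = 0.0682). Of these markers 1 fell without M-CSF replicate 1 or RANKL replicate 1.

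**Figure D1:**
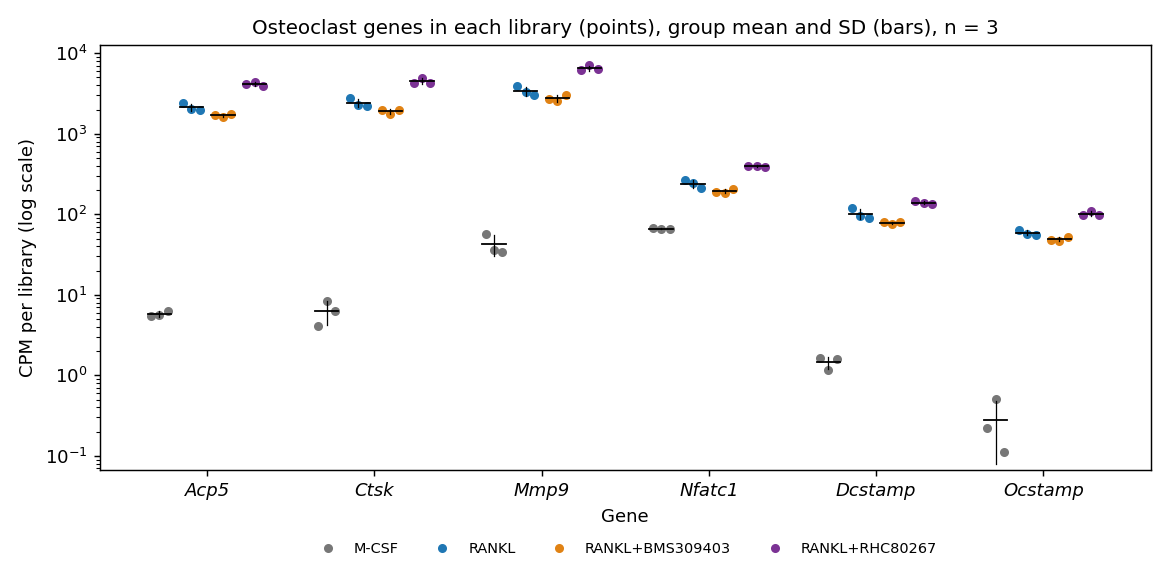
Levels of 6 osteoclast genes in each library, in CPM on a log axis, by culture group, with the mean and SD of 3 libraries. Acp5 averaged 5.77 CPM with M-CSF, 2140 with RANKL, 1690 with RANKL and BMS309403 and 4140 with RANKL and RHC80267.

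The comparison of BMS309403 with RANKL alone asks what inhibition of FABP4 changes during the response to RANKL. The changes were small. All 24 interferon response genes rose, with Ifit3, an antiviral gene, at 125 ± 8.18 against 74.3 ± 8.55 CPM (SD, n = 3). Among osteoclast genes, Acp5 was at 1690 ± 73.0 against 2140 ± 211 CPM and Dcstamp, a fusion gene, at 78.2 ± 3.05 against 102 ± 14.9 CPM. Among macrophage genes, C1qa, a complement component, was at 641 ± 30.7 against 498 ± 14.5 CPM. Fabp4 itself was at 41.6 ± 6.29 against 36.4 ± 6.77 CPM and was not called.

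Of the genes tested, 426 were higher and 457 lower, but only 2 and 6 of them by more than 2-fold. Without RANKL replicate 1 the counts were 152 and 111, without BMS309403 replicate 2 they were 171 and 145, and 292 were lower without BMS309403 replicate 1. Acp5 changed by −0.35 ± 0.05 on the log2 scale (SE, adjusted p = 0.000549), Nfatc1 by −0.31 ± 0.06 (adjusted p = 0.00181) and Dcstamp by −0.38 ± 0.07 (adjusted p = 0.00175), which became −0.26, −0.23 and −0.25 without RANKL replicate 1 and stayed called. Ctsk changed by −0.35 ± 0.08 (adjusted p = 0.00962) and Ocstamp by −0.28 ± 0.06 (adjusted p = 0.00961), but both calls are lost without RANKL replicate 1 (−0.25 and −0.22) or without BMS309403 replicate 2, and that of Ctsk also with DESeq2. Mmp9 was at −0.31 ± 0.10 and was not called (adjusted p = 0.0682), though it was called with no filter, limma-voom or only the groups compared and without RANKL replicate 3 (−0.39). Without RANKL replicate 1 it was at −0.20 (adjusted p = 0.399). Fabp5 rose by 0.29 ± 0.07 (adjusted p = 0.0136), a call lost with DESeq2 and without RANKL replicate 1 or 2 or BMS309403 replicate 2. The fixed genes Fabp4, at 0.19 ± 0.12, Dagla, Daglb, Tnfrsf11a and Csf1r were not called, except that Tnfrsf11a, at −0.12, was called at −0.17 without RANKL replicate 3. Without RANKL replicate 1, Fabp4 was at 0.06 and Tnfrsf11a at −0.07, and without RANKL replicate 3 or BMS309403 replicate 3 Fabp4 was at 0.33 and 0.32. Tnfrsf11a was at −0.07 also without BMS309403 replicate 1. Among genes that meet the naming rule, the highest changes were Ifit3 at 0.75, Ifit2 at 0.67, Iigp1 at 0.65, Ifi206 at 0.64, Isg15 at 0.63 and Ifi213 at 0.63. All are known as interferon-induced. Among the lowest by that rule were Krt7, a keratin, at −0.67, Aspm, a spindle protein, at −0.64 and Chst11, a chondroitin sulfotransferase, at −0.61. Lat, Ghr and Corin were at −0.77, −0.66 and −0.65, and each of these calls is lost when some library is left out (for Lat BMS309403 replicate 2, for Ghr RANKL replicate 1 or BMS309403 replicate 3, for Corin RANKL replicate 1 or 2 or BMS309403 replicate 2).

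With an estimated correlation, the calls of 3 lists held, each at a camera adjusted p of 0.0338. The adjusted p-values that follow are at the preset correlation. The 24 interferon genes rose with a median of 0.48, also when adjusted over the list alone (camera adjusted p = 9.79e-50), with Isg15 (gene 100038882, chromosome 4, 156199424 to 156200818) at 0.63 ± 0.08 and the chemokine gene Cxcl10 at 0.58 ± 0.07. Of 23 macrophage genes 10 rose (14 adjusted over the list alone, adjusted p = 1.96e-15), among them Fcgr1, an antibody receptor, at 0.44, C1qa at 0.36, Ms4a7 at 0.33 and C1qb at 0.31. Of 17 antigen presentation genes 7 rose (11 rose and 1 fell adjusted over the list alone, adjusted p = 7.83e-08), with B2m at 0.26 and Cd86 at 0.24, and 4 rose without RANKL replicate 1.

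The other lists had calls only at the preset correlation. In the resorption list 9 of 23 fell (14 adjusted over the list alone, adjusted p = 3.79e-09, adjusted p = 0.137 with an estimated correlation), with Car2, carbonic anhydrase, at −0.44, Src at −0.32 and Ckb at −0.32. Its median was −0.26, and −0.14 with 4 members fallen without RANKL replicate 1, as against −0.17 and 4 without BMS309403 replicate 2. Of 19 fusion genes 8 fell (10 fell and 1 rose adjusted over the list alone, adjusted p = 1.47e-07, adjusted p = 0.0877 with an estimated correlation), with Siglec15 at −0.44 and Itgav at −0.30, and 4 fell without RANKL replicate 1 or BMS309403 replicate 2. In the transcription list 9 of 29 fell and 2 rose (12 and 4 adjusted over the list alone, adjusted p = 0.000161, adjusted p = 0.139 with an estimated correlation), with Fosl2 at −0.43, Jdp2 at −0.42 and Oscar at −0.42, but edgeR called no risen member without RANKL replicate 1 or 2 or BMS309403 replicate 1 or 2 (3, 4, 5 and 3 at an unadjusted p below 0.05). Of 30 mitosis and DNA replication genes 12 fell (18 adjusted over the list alone, adjusted p = 3.66e-14, adjusted p = 0.137 with an estimated correlation), with Cdc20 at −0.56, Cenpf at −0.53, Ccnb2 at −0.48 and Ccnb1 at −0.46, and 7 fell without RANKL replicate 1 or BMS309403 replicate 2. Of 32 oxidative phosphorylation genes 7 fell (12 adjusted over the list alone, adjusted p = 7.52e-06, adjusted p = 0.313 with an estimated correlation), and 1 without RANKL replicate 1, 4 without BMS309403 replicate 1 or 3, and 0 by edgeR without BMS309403 replicate 2 (9 at an unadjusted p below 0.05). Of 18 V-ATPase genes 3 fell (4 adjusted over the list alone, adjusted p = 0.0122, adjusted p = 0.313 with an estimated correlation), and 1 without RANKL replicate 1 or BMS309403 replicate 2. The V-ATPase list is no longer called without BMS309403 replicate 2 (adjusted p = 0.0723).

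The remaining called lists hold lysosome, antioxidant and lipid genes. Of 25 lysosome genes 10 rose (12 adjusted over the list alone, adjusted p = 6.59e-10, adjusted p = 0.137 with an estimated correlation), with Ctsb, a lysosomal protease, at 0.23 and Lamp1, a lysosomal membrane protein, at 0.22, and 2 rose without RANKL replicate 1 or BMS309403 replicate 2. Of 16 NRF2 targets 4 rose (6 adjusted over the list alone, adjusted p = 0.000292, adjusted p = 0.165 with an estimated correlation), led by Fth1, a ferritin, at 0.28 and Prdx1 at 0.23, and 2 rose without RANKL replicate 1. Of 12 targets of the sterol receptor LXR 6 rose, as also adjusted over the list alone (adjusted p = 0.00262, adjusted p = 0.137 with an estimated correlation), with Apoe at 0.26 and Arl4c at 0.19, and 2 rose without RANKL replicate 1 or BMS309403 replicate 2. Of 5 fatty acid binding proteins 1 rose, Fabp5 (1 adjusted over the list alone, adjusted p = 0.0401, adjusted p = 0.181 with an estimated correlation), and the list is not called without RANKL replicate 1 (adjusted p = 0.0759) or BMS309403 replicate 1 or 2 (adjusted p = 0.0950 and 0.0918). Of 24 cholesterol synthesis genes 1 fell, and 0 adjusted over the list alone (Hmgcs1 at −0.14, camera adjusted p = 0.0323, adjusted p = 0.482 with an estimated correlation). The call of Hmgcs1 is lost with DESeq2, RLE factors, no filter, the stricter filter, limma-voom or only the groups compared, and in 5 of the 6 fits that left out a library, all but that without RANKL replicate 3. The list loses its call without RANKL replicate 1 or 3 (adjusted p = 0.0705 and 0.0674) or BMS309403 replicate 1 or 3 (adjusted p = 0.0576 and 0.119).

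The comparison of RHC80267 with RANKL alone asks what inhibition of diacylglycerol lipase changes during the response to RANKL. All 24 interferon response genes fell, most of them several-fold: Ifit3 was at 5.10 ± 0.697 against 74.3 ± 8.55 CPM and Cxcl10 at 3.03 ± 0.619 against 32.0 ± 2.68 CPM (SD, n = 3). Among antigen presentation genes, the class II chaperone Cd74 was at 557 ± 48.4 against 1490 ± 68.3 CPM. Among osteoclast genes, Acp5 rose to 4140 ± 217 from 2140 ± 211 CPM, Ctsk to 4520 ± 414 from 2420 ± 290 CPM and Calcr to 87.2 ± 9.38 from 21.7 ± 1.24 CPM. Fabp5 fell from 807 ± 87.8 to 482 ± 6.99 CPM.

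Of the genes tested, 3272 were higher and 2802 lower, 203 and 358 of them by more than 2-fold. Acp5 rose by 0.95 ± 0.05 on the log2 scale (SE, adjusted p = 5.76e-12), Ctsk by 0.90 ± 0.08 (adjusted p = 7.27e-09), Mmp9 by 0.93 ± 0.10 (adjusted p = 1.63e-07) and Nfatc1 by 0.73 ± 0.06 (adjusted p = 5.05e-10). Ocstamp rose by 0.78 and Dcstamp by 0.46. Fabp5 fell by 0.74 on the log2 scale (SE 0.07, adjusted p = 1.33e-08) and Dagla by 0.68 (SE 0.11, adjusted p = 1.88e-05). Daglb was at −0.11 ± 0.04 (adjusted p = 0.0365), a call lost with DESeq2 and in 5 of the 6 fits that left out a library of these groups, all but the fit without RANKL replicate 1. Fabp4 at −0.06 ± 0.12, Tnfrsf11a at −0.04 and Csf1r at −0.03 were not called, and with 1 library left out Fabp4 ranged from −0.19 (without RANKL replicate 1) to 0.07 (without RANKL replicate 3) and Tnfrsf11a from −0.09 (without RANKL replicate 3) to 0.01 (without RANKL replicate 1). By the naming rule, the highest changes were Marco, a scavenger receptor, at 2.72, Cd55, a complement regulator, at 2.68, and Fkbp5, a co-chaperone of steroid receptors, at 2.37. Next were Slc13a3, a dicarboxylate transporter, at 2.08, and Col1a2 and Calcr at 2.01. Col1a2 was at 24.6 CPM in RHC80267 replicate 1 and at 5.34 and 5.21 CPM in the other two, and its change was 0.86 without replicate 1. Besides Hmga1b at −5.78, the lowest by that rule were Ifit3b at −3.90, Ifit3 at −3.87, Ifit2 at −3.79, Ifit1bl1 at −3.64 and Ifit1 at −3.45.

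With an estimated correlation, the calls of 2 lists held, at camera adjusted p = 0.00499 for the interferon response and 0.00079 for antigen presentation. The adjusted p-values that follow are at the preset correlation. The 24 interferon genes fell with a median of −2.87, also when adjusted over the list alone (camera adjusted p = 1.59e-109), with Cxcl10 at −3.39 ± 0.12, Rtp4 at −3.16, Oas3 at −3.15 and Rsad2 at −3.14. Of 17 antigen presentation genes 16 fell and 1 rose, as also adjusted over the list alone (adjusted p = 1.23e-29), with H2-Eb1 at −1.68, H2-Ab1 at −1.47, Cd74 at −1.42 and the co-stimulator Cd86 at −1.30. The 1 risen gene loses its call without RANKL replicate 3 or RHC80267 replicate 3.

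At the preset correlation, 18 of 23 resorption genes rose and 4 fell, as also adjusted over the list alone (adjusted p = 3.48e-11, adjusted p = 0.0796 with an estimated correlation), with Calcr at 2.01, Itgb3, the osteoclast integrin, at 1.22 and Ckb at 0.92. Of 19 fusion genes 10 rose and 6 fell (10 and 8 adjusted over the list alone, adjusted p = 0.0378, adjusted p = 0.346 with an estimated correlation), with Myo10 at 0.90 but Cd44 at −0.62, and the call is lost without RANKL replicate 2 or 3 (adjusted p = 0.0502 and 0.0539). In the transcription list 12 of 29 rose and 8 fell (13 and 9 adjusted over the list alone, adjusted p = 0.0424, adjusted p = 0.346 with an estimated correlation), with Oscar at 1.27 and Fosl2 and Ppargc1b at 0.68. There 5 fell without RANKL replicate 2, and the call is lost without RANKL replicate 2 or 3 (adjusted p = 0.0590 and 0.0629) or RHC80267 replicate 1 (adjusted p = 0.0742). Of 18 V-ATPase genes 13 rose and 1 fell, as also adjusted over the list alone (adjusted p = 0.00149, adjusted p = 0.282 with an estimated correlation). Of 18 negative regulators of osteoclast formation 13 fell and 2 rose (13 and 4 adjusted over the list alone, adjusted p = 1.25e-06, adjusted p = 0.0523 with an estimated correlation), among them the repressors Id2 at −1.17, Bcl6 at −0.79 and Rbpj at −0.78, and 1 rose without RANKL replicate 2. All 32 oxidative phosphorylation genes rose, also when adjusted over the list alone, with a median of 0.24 (adjusted p = 5.01e-08, adjusted p = 0.282 with an estimated correlation). Of 30 mitosis and DNA replication genes 25 rose and 1 fell (26 and 2 adjusted over the list alone, adjusted p = 1.79e-05, adjusted p = 0.346 with an estimated correlation), with Aurkb, a mitotic kinase, at 0.64, and 2 fell without RANKL replicate 3. Of 20 genes of ER stress and the amino acid response 16 rose and 2 fell, as also adjusted over the list alone (adjusted p = 0.00148, adjusted p = 0.0523 with an estimated correlation), with Asns, asparagine synthetase, at 0.88 and Herpud1 at 0.62, and 1 fell without RANKL replicate 1 or 2 or RHC80267 replicate 3.

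Cholesterol synthesis genes fell, 16 of 24, as also adjusted over the list alone (adjusted p = 6.52e-12, adjusted p = 0.0569 with an estimated correlation), with Cyp51, a sterol demethylase, at −1.05 and Hmgcs1 at −0.67. Of 12 LXR targets 6 fell and 2 rose, as also adjusted over the list alone (adjusted p = 0.0127, adjusted p = 0.256 with an estimated correlation), with Arl4c at −1.09 and the cholesterol exporter Abca1 at −0.62. The macrophage list was mixed: 11 of 23 fell and 7 rose, as also adjusted over the list alone (adjusted p = 0.0238, adjusted p = 0.346 with an estimated correlation), with Fcgr1 at −1.29 and Marco at 2.72. In the NF-kB list 11 of 24 fell and 7 rose (11 and 8 adjusted over the list alone, adjusted p = 0.0432, adjusted p = 0.346 with an estimated correlation), with Il1rn at −1.54, and the call is lost without RANKL replicate 1 (adjusted p = 0.0503) or RHC80267 replicate 2 (adjusted p = 0.0917). Markers of other cell types moved in the same libraries. Of 15 neutrophil and granulocyte precursor markers 11 fell (12 adjusted over the list alone, adjusted p = 4.81e-05, adjusted p = 0.346 with an estimated correlation), with Fcnb at −2.00 and Elane at −1.15. Of 8 lymphocyte markers 5 fell and 1 rose, as also adjusted over the list alone (adjusted p = 0.000774, adjusted p = 0.0569 with an estimated correlation), with Il7r at −1.80, and the 1 risen marker loses its call without RANKL replicate 1, 2 or 3 or RHC80267 replicate 1 or 2. Of 12 dendritic cell markers 7 fell and 1 rose, the osteoclast fusion gene Dcstamp, as also adjusted over the list alone (adjusted p = 0.0401, adjusted p = 0.362 with an estimated correlation), a call lost without RANKL replicate 1 (adjusted p = 0.118). Of 9 stromal and osteoblast markers 5 rose and 1 fell, as also adjusted over the list alone, and the list was called only without RHC80267 replicate 3 (adjusted p = 0.0438 against 0.183 with all libraries). The 1 fallen stromal marker loses its call without RHC80267 replicate 2.

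**Figure D2:**
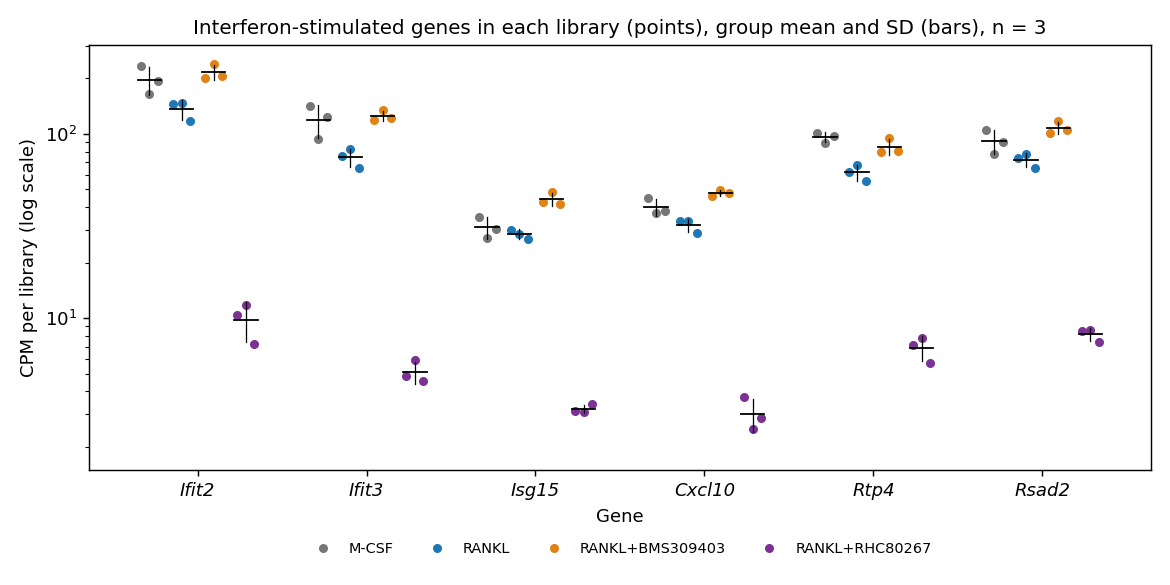
Levels of 6 interferon-induced genes in each library, in CPM on a log axis, by culture group, with the mean and SD of 3 libraries. Ifit3 averaged 74.3 CPM with RANKL, 125 with RANKL and BMS309403 and 5.10 with RANKL and RHC80267.

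The comparison of RHC80267 with BMS309403 asks where the cultures with the 2 inhibitors, both at 1 µM for 2 days, differ. Among osteoclast genes, Acp5 with RHC80267 was at 4140 ± 217 against 1690 ± 73.0 CPM, and Itgb3 at 299 ± 26.5 against 101 ± 7.66 CPM (SD, n = 3). Interferon genes were lower, with Isg15 at 3.22 ± 0.177 against 44.2 ± 3.55 CPM. Fabp5 was at 482 ± 6.99 CPM with RHC80267 and 984 ± 79.1 CPM with BMS309403.

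Of the genes tested, 3660 were higher and 3099 lower with RHC80267, 387 and 389 of them by more than 2-fold. Acp5 was 2.46-fold higher (adjusted p = 2.36e-14) and Ctsk 2.38-fold (adjusted p = 2.59e-11). On the log2 scale Nfatc1 differed by 1.03 ± 0.06 (SE, adjusted p = 1.13e-12), Isg15 by −3.78 ± 0.11 (adjusted p = 1.43e-16) and Fabp5 by −1.03 ± 0.07 (adjusted p = 4.75e-11). Fabp4 differed by −0.25 ± 0.12 and was not called (adjusted p = 0.0696), though it was called with no filter, with only the groups compared, and without BMS309403 replicate 3 (−0.40) or RHC80267 replicate 2 (−0.34). It was at −0.14 without RHC80267 replicate 1. The highest values by the naming rule were Col1a1 at 2.88, Fkbp5 at 2.55, Cd55 at 2.44, Sema3a at 2.36, Calcr at 2.27 and Slc13a3 at 2.26. Without RHC80267 replicate 1 Col1a1 was at 1.90. Of 23 resorption genes 19 were higher and 4 lower, as also adjusted over the list alone (camera adjusted p = 9.79e-14, adjusted p = 0.0857 with an estimated correlation). All 24 interferon genes were lower, also when adjusted over the list alone (adjusted p = 2.62e-115), and 16 of 17 antigen presentation genes, as also adjusted over the list alone (adjusted p = 1.12e-29), and both calls held with an estimated correlation (adjusted p = 0.00433 and 0.000812). Of 12 LXR targets 7 were lower and 2 higher, as also adjusted over the list alone (adjusted p = 0.00168, adjusted p = 0.128 with an estimated correlation), with Arl4c at −1.28 and Abca1 at −0.83, and 1 was higher without BMS309403 replicate 2 or RHC80267 replicate 1. Markers of other cell types differed too. Of 15 neutrophil and granulocyte precursor markers 11 were lower, as also adjusted over the list alone (adjusted p = 0.00174, adjusted p = 0.431 with an estimated correlation), with Fcnb at −1.88 and Camp at −1.22. Of 8 lymphocyte markers 5 were lower, as also adjusted over the list alone (adjusted p = 0.000466, adjusted p = 0.0857 with an estimated correlation), with Il7r at −2.00 and Cd4 at −1.40. Of 9 stromal and osteoblast markers 6 were higher and 1 lower, as also adjusted over the list alone (adjusted p = 0.227), and the 1 lower marker loses its call without RHC80267 replicate 2.

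The inhibitors were also compared by what they did to the genes that respond to RANKL. Of the 3819 genes higher with RANKL, 398 fell and 30 rose with BMS309403, with a median log2 fold change of −0.07 over the 3819. Of the 3628 genes lower with RANKL, 335 rose and 10 fell, with a median of 0.05. Without RANKL replicate 1 these counts were 100, 9, 110 and 3, and without BMS309403 replicate 2 they were 126, 8, 136 and 4. The 398 became 259 without BMS309403 replicate 1, the 30 became 12 without RANKL replicate 2 and 19 without BMS309403 replicate 1, and the 10 became 5 without RANKL replicate 2 or BMS309403 replicate 1 and 6 without RANKL replicate 3. For RHC80267, 1468 of the genes higher with RANKL rose and 728 fell (median 0.08), and of those lower with RANKL 1105 fell and 829 rose (median −0.02). These comparisons share the RANKL libraries. With BMS309403 libraries drawn from the RANKL means, the median over the genes higher with RANKL was −0.00977 to −0.00554 in 20 simulations, and that over the lower genes 0.00505 to 0.0109. The RHC80267 median of −0.02 lies outside the simulated range of 0.00550 to 0.0101. It lay further from that range with RANKL libraries split between the comparisons (−0.04) and with a stricter filter (−0.03).

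Across the 12168 genes, which are not independent replicates, the fold changes with BMS309403 and RHC80267 had a Pearson correlation of −0.14. The simulations with shared RANKL libraries gave 0.468 to 0.538, but they held no inhibitor effect. Real changes widen the spread of the fold changes and lower the correlation that shared libraries give, so these correlations are not comparable. The covariance, which is not scaled by that spread, was −0.0130 against a simulated 0.00899 to 0.0114. Without RANKL replicate 1 the correlation was 0.02, and over the genes called with RANKL it was −0.23. Among called genes, 286 were higher with BMS309403 and lower with RHC80267 (98.1 would be shared by independent lists) and 316 were lower with BMS309403 and higher with RHC80267 (122.9). In a common direction, 44 were higher with both (114.6) and 42 lower with both (105.2). Without RANKL replicate 1 these 4 counts were 122, 92, 9 and 4 (33.0, 28.0, 38.3 and 24.1 for independent lists), and without BMS309403 replicate 2 they were 116, 107, 15 and 8 (41.1, 36.2, 42.7 and 34.8). The 316 became 199 without BMS309403 replicate 1 (73.3), the 44 became 68 without RANKL replicate 3, and the 42 became 19 without RANKL replicate 2 (64.0) and 15 without BMS309403 replicate 3.

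**Figure D3:**
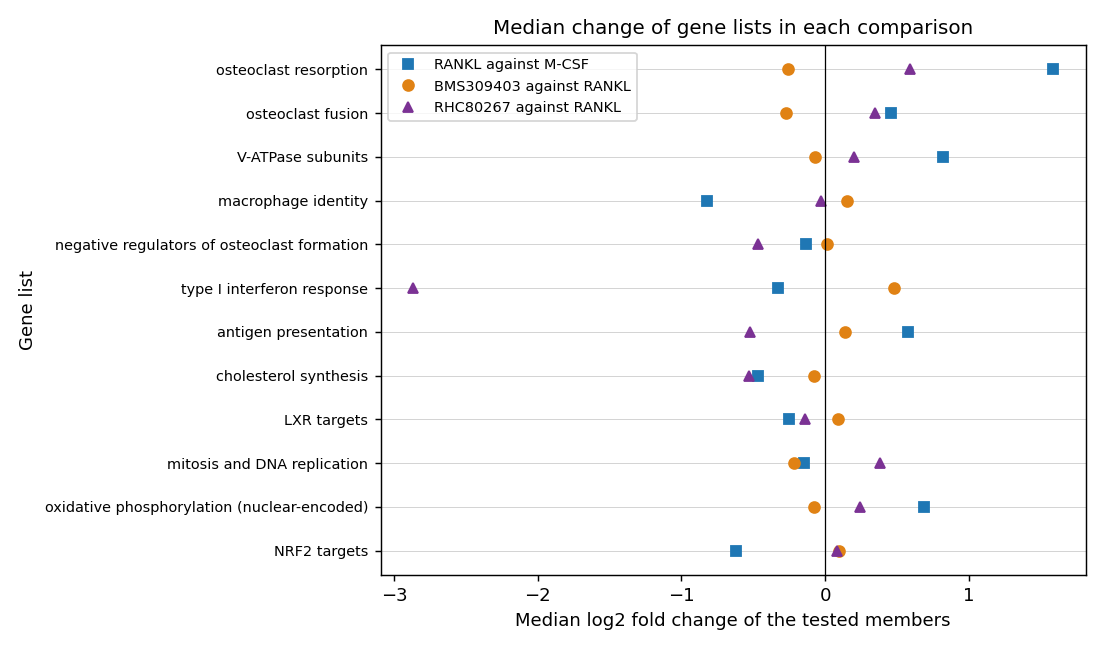
Median log2 fold change of the tested members of 12 gene lists in the comparisons of RANKL with M-CSF, BMS309403 with RANKL and RHC80267 with RANKL. The interferon list stands at 0.48 with BMS309403 and at −2.87 with RHC80267.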

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

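The tests of explanations given here, on other cell types, glucocorticoid receptor targets, stromal genes other than collagens, RANKL replicate 1, the shared RANKL libraries and a smaller RANKL response, were chosen only after the result was seen.

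For 10 of the 31 lists camera called opposite directions for BMS309403 and RHC80267 against RANKL, and the direct comparison of the inhibitors was called too, though not all members moved that way (of macrophage genes with RHC80267, 11 fell and 7 rose). Median log2 differences, RHC80267 over BMS309403, were −3.33 for the interferon response and −0.70 for antigen presentation, and these 2 calls held with an estimated correlation. The other 8 did not hold it. They were resorption at 0.89, mitosis and DNA replication at 0.62, fusion at 0.35, oxidative phosphorylation at 0.33, V-ATPase subunits at 0.25 and osteoclast transcription and RANK signalling at 0.08, with macrophage identity at −0.19 and LXR targets at −0.13.

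The 24 interferon genes fell with RHC80267 by a median log2 fold change of −2.87. If contaminating cells of other types carried these transcripts, their loss would lower their markers about as far. The median of 45 granulocyte, lymphocyte, dendritic and mast cell or megakaryocyte markers was −0.76 (95% bootstrap interval −1.05 to −0.38, which takes the genes as independent), with 28 fallen and 3 risen, among them the fusion gene Dcstamp. By list the medians were −1.15 for lymphocyte, −0.76 for neutrophil, −0.74 for mast cell, basophil and megakaryocyte and −0.41 for dendritic cell markers. This argues against a common loss of all these cells as the whole cause. The loss of a single cell type that carried these transcripts is not excluded, since some markers, such as Fcnb and Il7r, fell further than these medians. Nor does the test cover lost cells that had acted on the interferon genes of the macrophages. A candidate explanation, raised by the rise of Fkbp5, is glucocorticoid receptor activity: 16 of 29 tested targets rose and 7 fell (camera p = 0.00107 with an estimated correlation), but 19 of the 29 had been seen before the list was written. Of the 10 unseen ones 4 rose and 5 fell, with a median of −0.03 (camera p = 0.572 with an estimated correlation). The unseen targets thus showed no shift upward, and glucocorticoid receptor activity cannot be told apart from other causes. An effect of RHC80267 through diacylglycerol lipase stays open and untested, since no other inhibitor of the enzyme was used.

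Collagen genes were higher with RHC80267, chiefly in RHC80267 replicate 1, where Col1a1 was at 21.1 CPM against 6.10 and 4.72 CPM in the other two. That library was picked from these and other stromal markers, so further stromal genes were listed before their values were seen, of which 21 were tested, 7 of them collagens. Of the 14 that are not collagens, 10 had their highest level of all 12 libraries there, against 12.2% of all tested genes (1-sided exact binomial p = 4.53e-07, which takes the genes as independent), as stromal cells carried over mainly into that culture would give. An effect of RHC80267 on stromal genes would also place high levels in its libraries, so this p does not separate the 2. Of the 21 further genes 12 rose and 1 fell, and 5 rose without that library (median 1.08 and 0.26). Without that library Col1a1 changed by 1.01 (adjusted p = 0.0104) in place of 1.98, Col3a1 by 1.36 in place of 2.19 and Sparc by 0.84 in place of 1.97 (adjusted p = 0.0567), and 4 markers were called higher in place of 5. What raised collagen genes in the other two libraries stays open, and so does an effect of RHC80267 on stromal cells, untested.

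The osteoclast genes called lower with BMS309403 were weighed against RANKL replicate 1, where Acp5 was at 2387 CPM against 2046 and 2000 CPM in the other two. Over all 41 tested resorption and fusion genes the median was −0.26, and −0.15 without that library (95% bootstrap interval −0.20 to −0.07, which takes the genes as independent), with 8 called lower in place of 16, so that library accounts for part of the pattern but not all of it. Of the osteoclast genes fixed before the data were examined, Acp5, Nfatc1 and Dcstamp stayed called without it (−0.26, −0.23 and −0.25), Ctsk and Ocstamp did not (−0.25 and −0.22, adjusted p = 0.0930 and 0.0998), and Mmp9 and Tnfrsf11a were called neither with it nor without it. Without it both lists were called only at the preset correlation (adjusted p = 5.77e-08 and 5.91e-07 for resorption and fusion, but 0.130 and 0.0553 with an estimated one). The median of −0.069 over genes higher with RANKL, which are not osteoclast genes alone, lies below the 20 values simulated with shared RANKL libraries. It was −0.074 with RANKL libraries split between the comparisons. The simulations drew each gene independently, so they do not cover a shift of a whole RANKL library. With RANKL libraries split between the comparisons, 94.9% of genes called with both moved against RANKL, which may reflect a smaller RANKL response as a whole (RHC80267: 33.1%). Resorption, fusion and macrophage lists moved against RANKL. But at the preset correlation antigen presentation was called higher, and cholesterol synthesis lower, with both RANKL and BMS309403. The interferon median was 0.48 with BMS309403 and −0.33 with RANKL. Inhibition of FABP4 stays open as the origin of the pattern, untested.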

How the results depend on the processing

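No alternative here was chosen after a result was seen. Of 6767 values of named genes (522 gene and comparison combinations), 6551 kept direction and call, 184 lost the call, 32 gained it and 0 reversed. Of 78 named genes called with BMS309403, 32 lost the call in some fit without a library (28 without RANKL replicate 1) and 6 with another setting, 4 of them with DESeq2. In the comparison of RANKL with M-CSF, 6 of 124 lost it without some library, against 6 of 126 for RHC80267 with RANKL and 5 of 128 for RHC80267 with BMS309403. Counts of called genes stayed within 1.5 times under DESeq2, RLE factors, both filters, limma-voom, only the groups compared and the term for the replicate number.

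The median effect of RHC80267 on genes higher with RANKL was 0.112 with RANKL libraries split. On genes lower with RANKL it was −0.038 split and −0.032 with the stricter filter. The cause was not tested. Lists called with an estimated correlation numbered 5 for RANKL (14 at the preset), 3 for BMS309403 (14), 2 for RHC80267 (17) and 2 for RHC80267 against BMS309403 (16), and with fry 27, 12 (4 lost, 2 gained), 24 and 25. The size of the estimated correlations was not examined, and fry does not compare a list with other genes.

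With each library left out, RANKL gave 3507 to 3606 genes higher and 3321 to 3447 lower, BMS309403 152 to 472 and 111 to 538, RHC80267 2830 to 3097 and 2483 to 2663, and RHC80267 against BMS309403 3008 to 3367 and 2804 to 3196. The lowest counts for BMS309403 were without RANKL replicate 1. The correlation of both inhibitors' changes ranged from −0.125 to 0.017 (the latter without RANKL replicate 1). Medians ranged from −0.086 to −0.059 and from 0.049 to 0.069 for BMS309403 on genes higher and lower with RANKL, and from 0.076 to 0.097 and from −0.024 to −0.01 for RHC80267. Lists called ranged from 13 to 15, 12 to 15, 15 to 19 and 16 to 17. Replicate numbers did not pair the libraries: residual correlations of equal numbers in different groups were −0.08 to 0.09 and of different numbers −0.08 to 0.10. A term for the number gave 437 and 422 genes for BMS309403. With that term Fabp4 was called in RHC80267 against BMS309403, and Napepld, Rpl10 and Il7r with BMS309403. Hmgcs1 and Acaa2 with BMS309403 and Hba-a1 with RANKL were not called with it.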

Other observations

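The comparisons here were planned, except that Hmga1 and the interferon receptor genes were looked up only after the result was seen.

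Several lists the text has not yet described moved little or in both directions. Of 18 PPAR target and fatty acid oxidation genes 12 rose and 4 fell with RANKL, as also adjusted over the list alone (camera adjusted p = 0.105), with the mitochondrial enzymes Acaa2 at 1.00 and Etfdh at 0.85 but the fatty acid receptor Cd36 at −1.74. With RHC80267, 8 rose and 1 fell, as also adjusted over the list alone (adjusted p = 0.105), and 5 rose without RANKL replicate 2 and 2 fell without RHC80267 replicate 2 or 3. The highest was Angptl4, an inhibitor of lipoprotein lipase, at 1.98. Of 24 fatty acid and triglyceride synthesis genes 11 fell and 6 rose with RANKL, as also adjusted over the list alone (adjusted p = 0.0921), with the desaturase Fads1 at −0.94 and the malic enzyme Me1 at −1.15. Of 22 glycolysis and hypoxia genes 10 rose and 8 fell with RANKL, as also adjusted over the list alone (adjusted p = 0.354), and 0 were called with BMS309403 by edgeR. Of 17 immediate early and heat shock genes 8 fell and 4 rose with RANKL, as also adjusted over the list alone (adjusted p = 0.215), with Ier3 at −2.13, and 2 rose without M-CSF replicate 1 or RANKL replicate 3.

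Markers of other blood cells were measurable at low levels. Of 10 mast cell, basophil and megakaryocyte markers 5 fell and 1 rose with RHC80267, as also adjusted over the list alone (adjusted p = 0.0633), with the platelet genes Itga2b at −1.90 and Ppbp at −1.80 but Pf4 at 0.46, and 2 rose without RHC80267 replicate 1. That list was called without RANKL replicate 3 or RHC80267 replicate 3 (adjusted p = 0.0446 and 0.0438). Of 3 erythroid markers 2 rose and 1 fell with RANKL, as also adjusted over the list alone (adjusted p = 0.765), with a median of 0.55 and a mean of −0.42. The call of Hba-a1, at 1.13, is lost with DESeq2, no filter and without M-CSF replicate 2 or 3 or RANKL replicate 1, 2 or 3. The adipocyte list had 1 tested gene, Adig, higher with RANKL by a ratio of 50.3 (95% interval 8.63 to 2030) from 1 count in M-CSF. Of the 26 names of mitochondrially encoded genes, 0 are in the table.

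Hmga1b was at 8.31 ± 0.486 CPM with RANKL and at 0.145 ± 0.137 CPM with RHC80267 (SD, n = 3). Its paralog Hmga1 was at 260 ± 9.63 and 174 ± 1.09 CPM, and reads shared between the genes were not analysed here. The interferon receptor genes Ifnar1 and Ifnar2 changed by −0.38 ± 0.04 and −0.18 ± 0.04 with RHC80267 (SE, adjusted p = 8.93e-08 and 0.00123).

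In the authors' deposited table, at q-values below 0.05, 3100 genes are higher and 2902 lower with RANKL, 309 and 209 with BMS309403, 2140 and 2364 with RHC80267, and 2566 and 2738 in RHC80267 against BMS309403.

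The 6 libraries of each comparison can be split into 3 and 3 in 10 ways. The real split, 1 of the 10, called 7447 genes for RANKL, 883 for BMS309403, 6074 for RHC80267 and 6759 for RHC80267 against BMS309403. The highest count in any other split was 0, 1, 0 and 0. Every other split mixes libraries of both groups, so a difference between the groups adds to the spread within them and lowers the calls. These low counts therefore give no rate of false calls. With 10 splits a share below 0.05 cannot be reached.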
